A study of Mus musculus with 4 samples.

How the data were processed

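Nuclear RNA of NIH-3T3 cells with a doxycycline-inducible CDX2 transgene was measured in 4 directional RNA-seq libraries, 2 treated with doxycycline and 2 with solvent alone, each from 500000 cells treated for 6 h, per the labels' protocols. The dose is given as 500 ng/ml in the extraction protocol, while the treatment protocol gives the same figure per microlitre. Groups were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values may measure technical spread only.

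The submitters' processing notes name STAR 2.7.1a, SAMtools 1.10, Picard, HOMER 4.10, edgeR and limma and the mouse build mm10, with no role or order. The authors' deposited table is a comparison of the 2 groups with 40739 RefSeq transcripts of 25177 gene symbols, of which 24985 matched reference symbols. Its columns, per the file headers, are those of limma's output: a log2 fold change, a mean log2 expression, a moderated t score, a p-value, an adjusted p-value and a further log-odds column that was not used. The authors' deposited table also gives other columns used here, the start, end and exon length of each transcript in bases. No values per library were analysed here.

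Properties of the table were worked out from its values. The rows with the lowest mean expression are whole steps above the minimum (100% of 13001 rows, tolerance 0.01), as counts with 0.5 added per library would give on a log2 CPM scale. The 9211 rows at the minimum have no reads in any library and share a log2 fold change of -0.21, the trace of a 1.16-fold larger effective library with doxycycline. The p-values follow from t at 44446 degrees of freedom, which is 1 residual degree of freedom per row and so 3 model coefficients for 4 libraries. What the coefficient beyond the group means stands for is not given in the sources used here. The adjusted p-values are Benjamini-Hochberg values over 44446 rows, of which 3707 are not analysed here, 172 of them under 0.05. Level and fold account for 99.2% of the variance of the log standard error over 19541 rows with a mean log2 CPM of at least 2, so the spread was pooled over transcripts and p-values do not use each gene's own replicates. Isoforms with the same span and other exon lengths had different levels in all but 1 of 4808 groups, as for counts over exons. Transcript starts equalled those of GENCODE M21 in 41.1% of 33034 pairs and lay 1 base below in 2.25%, so coordinates count from 1.

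The planned tests needed counts per library, and the table holds none. So the count model, its alternatives, the replicate block, leaving out single libraries, the set test with an estimated correlation and the fry test were not run, and the authors' own test took their place. The standard error was computed as the log2 fold change divided by t. Each gene is represented by its transcript with the highest mean log2 CPM. Genes with a mean of at least 10 counts per library (mean log2 CPM of at least -2.12, or 0.230 CPM) were tested, 12355 in all, and called at an adjusted p of the authors under 0.05. Mean counts and mean CPM are geometric means throughout, taken from the mean log2 CPM. A gene without reads in either group therefore needs more counts in the other group to be tested. The median standard error of tested genes was 0.080 on the log2 scale (quartiles 0.069 and 0.12). Intervals at 95% assume normal errors. Rows that overlap another gene include those of Timp3 (Syn3), Zyx (Epha1), Nusap1 (Oip5), Stat2 (Apof), Cebpd (Spidr), Hoxd3 and Hoxd4 (each other), Tfap2a, Grhl2, Ceacam1, Cdh5, Hmga2, Nr2f1, Hoxb6 and Hoxd8 (noncoding or predicted genes), and their values are uncertain to the extent that reads are shared. Library depth is known only as the geometric mean of about 45700000 effective counts.

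Gene lists were fixed before the data were examined, 29 in all, and 26 had at least 5 tested members. They were tested with limma's cameraPR on the t scores at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists. An estimated correlation needs values per library, and a preset correlation of 0.05 was run in its place; the same 4 of 26 lists were called. Of 26 symbols of mitochondrially encoded genes, 0 are in the table used here. Older symbols in the lists were matched through reference synonyms.

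The rule for named genes was also fixed before the data were examined. It takes Cdx2, Cdx1 and Cdx4, then the 12 called genes with the largest rises and the 12 with the largest falls among those with a mean of at least 1 CPM, then up to 4 members of each list with the smallest p. Its condition that both doxycycline libraries lie on the same side of both controls was not applied, since it needs values per library. Predicted genes were to be skipped, and 0 were met in either direction. Other genes (Nr2f1, Icam1, Lif, Malat1, Klf9, Klf10, Utp4, Utp18, Cdh17, Cyp2c65, Hes7, Krt19, Gata3, Duox2 and Hox genes beyond those of the rule) were named after their values were seen. Of the genes the rule takes, 5 are not reported here.

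The gene calls were tested on simulated data with 200 of 12355 genes changed. At log2 changes of 0.25, 0.5 and 1, 29.6%, 81.3% and 95.5% of changed genes were recovered, with 4.31%, 4.84% and 5.26% false calls. The simulated errors were independent and normal with the authors' own standard errors, and p was adjusted over the 12355 genes. False calls near the threshold therefore follow from the construction and do not show whether those standard errors are too small. The set test found a shift of 1 in t of the mitotic list in 97.0% of 200 simulations, and 3.13% of null lists had a p under 0.05. Those t scores were simulated as independent with an SD of 1, against a robust SD of 2.08 over the genes tested. The set test scales by that spread, so 97.0% overstates how often such a shift is found in these data. The S phase list, with a mean t of 1.04, was not called (cameraPR adjusted p 0.185). Alternatives were another count floor (50), no floor, a stricter threshold (0.01), the longest transcript per gene, adjustment over the genes tested, a test against a 1.2-fold change, widened standard errors, removal of the expression trend, scaling to ribosomal protein genes, ranks in the set test and lists without shared members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.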

Results

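Nuclear RNA was sequenced from NIH-3T3 cells, an established line of mouse embryonic fibroblasts, that carried a doxycycline-inducible CDX2 transgene. CDX2 is a homeobox transcription factor known from intestinal epithelium, trophectoderm and the posterior axis of the embryo. 2 libraries came from cells given doxycycline at 500 ng/ml for 6 h, and 2 came from cells given solvent alone. The comparison of the 2 groups asks which nuclear transcripts differ after CDX2 induction. The values are those of the authors' deposited table, which gives 1 fold change per transcript and no value per library. Transcripts without reads all share 1 low value there, which implies an effective library of about 45700000 counts as a geometric mean over the 4 libraries. In all, 12355 genes reached a geometric mean of 10 counts per library and were tested. Such a mean is low when a group has almost no reads, so genes that rose from silence could stay untested.

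Cdx2 itself (NM_007673, mm10 chromosome 5, 147300900 to 147307249) was 124-fold higher with doxycycline in the authors' deposited table, with a 95% interval of 109-fold to 140-fold. Its log2 fold change there was 6.95 ± 0.091 (± standard error), and its adjusted p is listed at 0. The level and fold of the authors' deposited table correspond to 4.96 CPM without and 612 CPM with doxycycline. The table has 1 row for Cdx2 and does not part transgene from endogenous reads. Of its paralogues, Cdx4 is listed without reads in any library in the authors' deposited table, and Cdx1 held 1 count in 1 library.

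With doxycycline, 18 of 27 mesenchymal transcription factors fell, 9 of 18 cytokine and NF-kappaB genes fell and 6 rose, 6 HoxA genes fell while 5 HoxB genes rose, and 17 of 29 mitotic genes rose by small amounts, in the authors' deposited table. The largest fall among genes with a mean of at least 1 CPM was that of Hoxa3 (-2.34 ± 0.15, log2 fold change ± standard error), and the largest rise after Cdx2 was that of Mrgpre (2.57 ± 0.22), a Mas-related receptor, in the authors' deposited table. Vasn, which encodes the TGF-beta-binding membrane protein vasorin, with a mean level of 86.1 CPM over the libraries, fell by 2.13 on the log2 scale, or 4.37-fold, in the authors' deposited table. Of the 12355 genes tested, 1393 were higher and 1654 lower at an adjusted p under 0.05 in the authors' deposited table, which is 24.7% of them. At least 2-fold changes were fewer, with 73 genes higher and 134 lower, so 93.2% of the called genes changed by less than 2-fold. The median size of a called change was 0.37 on the log2 scale.

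**Figure D1:**
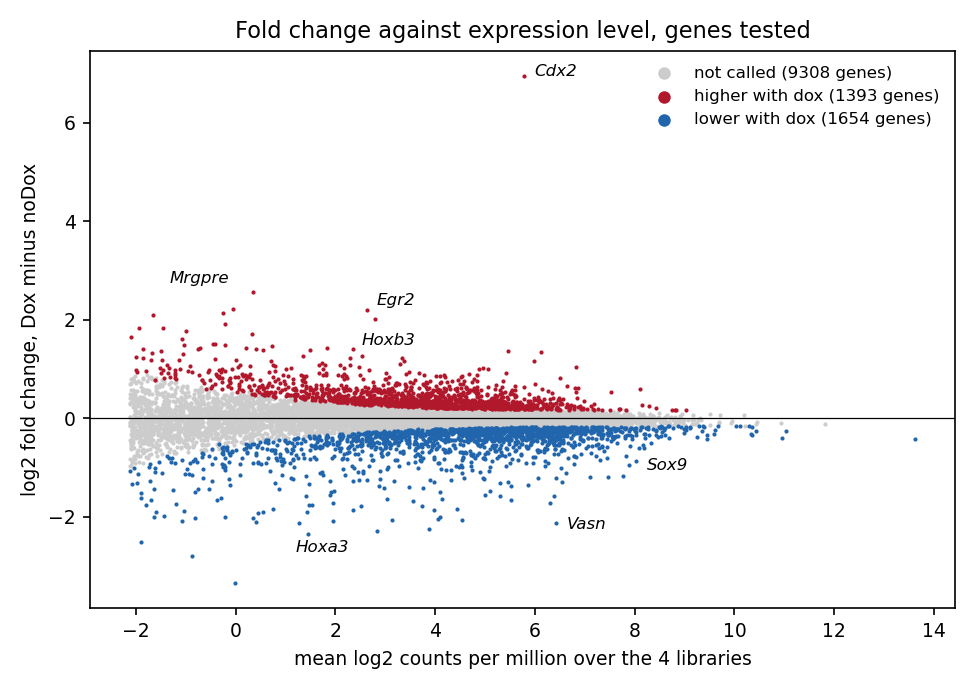
Log2 fold change (Dox minus noDox) against mean log2 CPM over the 4 libraries for the 12355 genes tested, from the authors' deposited table. Each point is 1 gene, and colours mark the 1393 genes higher, the 1654 lower and those not called at an adjusted p under 0.05. Cdx2 stands at 6.95, above all other genes.

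Egr2, a zinc finger factor of the immediate early response (chromosome 10, 67537869 to 67542188), rose by 2.21 ± 0.12 and Fgd3, a guanine nucleotide exchange factor of the FGD family, by 2.01 ± 0.10 in the authors' deposited table (adjusted p 4.04e-75 and 1.56e-82). C1qtnf1 (1.71 ± 0.20), a secreted C1q and TNF-related protein, Socs2 (1.46 ± 0.19), a suppressor of cytokine signalling, and Gpr85 (1.44 ± 0.20), an orphan receptor, followed in the authors' deposited table. Adgrg1 (1.42 ± 0.14), an adhesion receptor, Aldh3b1 (1.42 ± 0.19), an aldehyde dehydrogenase, Hoxb3 (1.40 ± 0.11), Arc (1.38 ± 0.15) and Chd7 (1.38 ± 0.18), a chromatin remodeller, complete, with Cdx2 and Mrgpre, the 12 largest rises among called genes with a mean of at least 1 CPM in the authors' deposited table.

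Ptx3, a pentraxin (-2.29 ± 0.11), Sema7a, a membrane-anchored semaphorin (-2.24 ± 0.084), and Ccl7, a chemokine (-2.13 ± 0.14), each fell more than 4-fold in the authors' deposited table. The vitamin D receptor gene Vdr (-2.03 ± 0.083), Fgd4 (-2.07 ± 0.10), a Cdc42 exchange factor, and Medag (-2.0 ± 0.082) fell by similar amounts in the authors' deposited table. Tmprss11f (-2.10 ± 0.19), Clec2d (-2.02 ± 0.18) and the noncoding RNA Ptgs2os2 (-2.09 ± 0.13) were lower as well in the authors' deposited table. Ptx3 lies within the span of Veph1 and Vasn overlaps Coro7. C1qtnf1 overlaps Gm11747 and Hoxb3 overlaps Hoxb3os, and the strand setting of the counting is not given in the sources used here, so these 4 values may share reads with their neighbours.

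**Figure D2:**
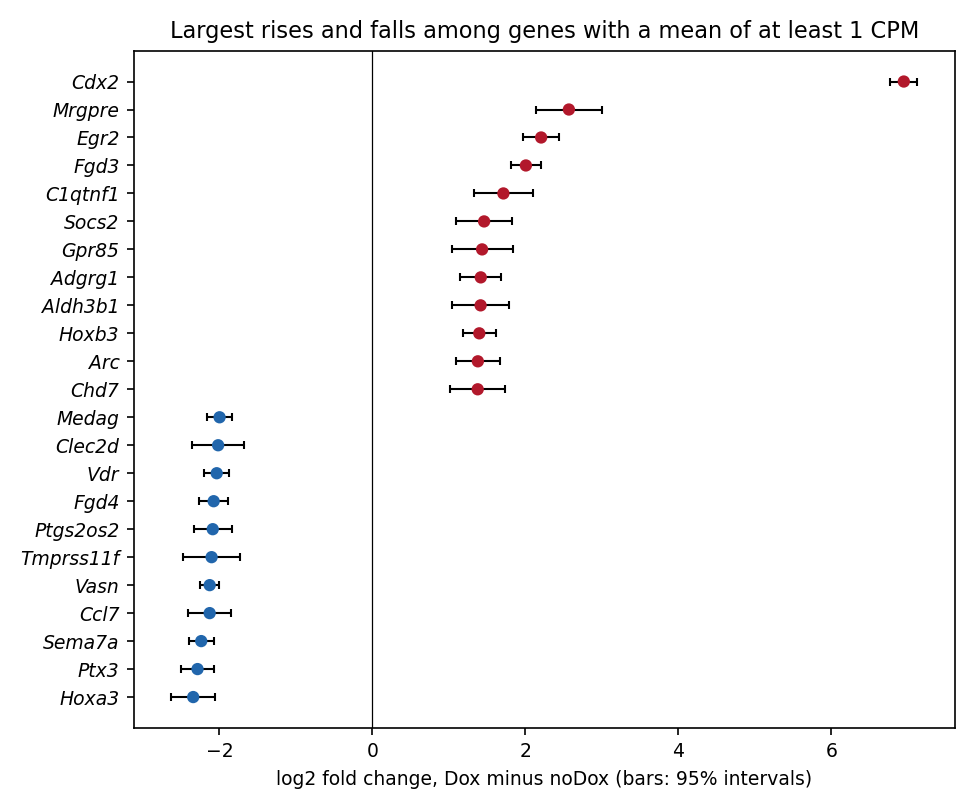
Log2 fold change (Dox minus noDox) of the 12 genes with the largest rises and of 11 of the 12 with the largest falls among called genes with a mean of at least 1 CPM, from the authors' deposited table. Points are fold changes and bars are 95% intervals. Rises other than that of Cdx2 lie between 1.38 and 2.57, and falls between -2.34 and -2.0.

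Mesenchymal transcription factors, the regulators typical of fibroblasts, fell together. Of 27 tested, 18 fell, 0 rose and 9 did not pass in the authors' deposited table, and 19 fell and 1 rose adjusted over the list alone. Osr1 (-1.63 ± 0.081), Nr2f2 (-1.24 ± 0.072), Prrx1 (-1.02 ± 0.065) and Sox9 (-0.87 ± 0.061) led the falls in the authors' deposited table. With all standard errors widened by 2.08, the robust SD of t over the genes tested, 14 were still called lower and 0 higher. That factor holds real changes as well as error, so it sets a stricter test and does not measure replicate spread. The list was lower than other genes (limma's cameraPR, preset correlation 0.01, adjusted p 5.95e-17 over 26 lists). Nr2f1, a paralogue of Nr2f2, stood at 0.16 ± 0.093 (adjusted p 0.324) in the authors' deposited table.

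Cytokine and NF-kappaB genes changed in both directions. Of 18 tested, 9 fell, 6 rose and 3 did not pass in the authors' deposited table, with 10 falls and 6 rises adjusted over the list alone. Il1rl1, the receptor of interleukin 33 (-1.72 ± 0.066), Csf1 (-1.22 ± 0.067), Ptgs2, which encodes cyclooxygenase 2 (-1.20 ± 0.062), and Ccl7 fell in the authors' deposited table. Lif (1.27 ± 0.11) and Icam1 (0.98 ± 0.30) rose in the authors' deposited table. With standard errors so widened, 9 were lower and 1 higher. The list was lower by cameraPR (adjusted p 1.94e-09), but not when ranks replaced the test statistics (adjusted p 0.379).

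Fibroblast matrix genes fell by smaller amounts. Of 28 tested, 16 fell, 1 rose and 11 did not pass in the authors' deposited table, with 17 falls and 2 rises adjusted over the list alone. Timp3 (-0.55 ± 0.061), an inhibitor of matrix proteases, Thbs2 (-0.54 ± 0.064) and the growth factor receptor gene Pdgfrb (-0.81 ± 0.073) fell in the authors' deposited table, whereas Pdgfra was the 1 gene that rose (0.92 ± 0.070). With widened standard errors, 4 of the 28 were lower and 1 higher. The list was lower by cameraPR (adjusted p 8.02e-04), a call that was lost once the trend of fold change with expression level was removed (adjusted p 0.220).

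Mitotic genes rose by small amounts. Of 29 tested, 17 rose, 1 fell and 11 did not pass in the authors' deposited table, and 21 rose and 1 fell adjusted over the list alone. Nusap1 (0.48 ± 0.070), Dlgap5 (0.34 ± 0.068) and Cdk1 (0.30 ± 0.065) rose and Anln (-0.33 ± 0.060), a cytokinesis gene, fell in the authors' deposited table. The list was higher by cameraPR (adjusted p 3.21e-04). With widened standard errors, 1 of the 29 genes was still called higher and 0 lower. S phase genes had 6 rises and 0 falls among 30 in the authors' deposited table, 7 and 0 adjusted over the list alone (Rrm2 0.35 ± 0.064, Cdc45 0.31 ± 0.069, set test adjusted p 0.185), and 0 in either direction with widened standard errors.

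**Figure D3:**
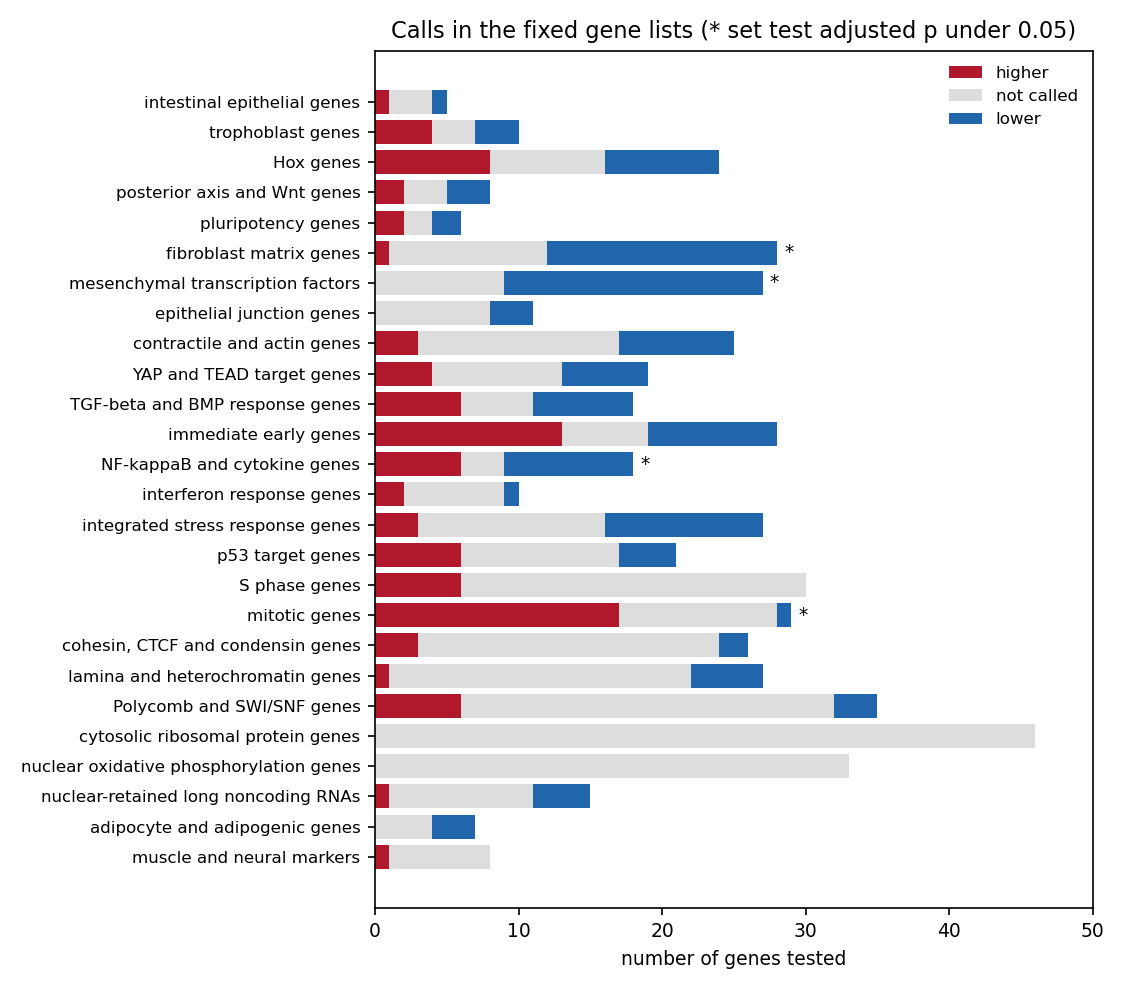
Number of genes tested (horizontal axis) in each list with at least 5 tested members, split into higher, not called and lower with doxycycline at an adjusted p under 0.05 in the authors' deposited table. Asterisks mark the 4 lists past the set test, of which the mesenchymal transcription factors have 18 of 27 genes lower and the mitotic genes 17 of 29 higher.

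Hox genes, which include known targets of CDX proteins, changed in both directions. Of 24 tested, 8 rose, 8 fell and 8 did not pass in the authors' deposited table, with 10 rises and 9 falls adjusted over the list alone. Hoxa2 (-1.90 ± 0.19), Hoxa3, Hoxa4 (-2.01 ± 0.23) and Hoxa5 (-1.72 ± 0.13) were among the 6 HoxA genes that fell, and 0 HoxA genes rose in the authors' deposited table. Of 7 HoxB genes tested, 5 rose and 0 fell in the authors' deposited table, with Hoxb3 (1.40 ± 0.11), Hoxb4 (1.2 ± 0.20) and Hoxb6 (0.85 ± 0.11) in front. With widened standard errors, 2 Hox genes were called higher (Hoxb3 and Hoxb6) and 4 lower (Hoxa2, Hoxa3, Hoxa4 and Hoxa5). Hoxd3 (0.91 ± 0.19) and Hoxd4 (0.90 ± 0.17) rose while Hoxd8 (-0.42 ± 0.081) and Hoxd9 (-0.41 ± 0.093) fell, and Hoxc6 (0.65 ± 0.14) was the 1 HoxC gene called, in the authors' deposited table. The row of Hoxa3 overlaps those of Hoxa4, Hoxa5 and Hoxa6, so these rows may share reads. The list as a whole was not called by the set test, which looks for a shift in 1 direction (adjusted p 0.723). Its median log2 fold change lay above 0 (0.19) and its mean below 0 (-0.10).

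**Figure D4:**
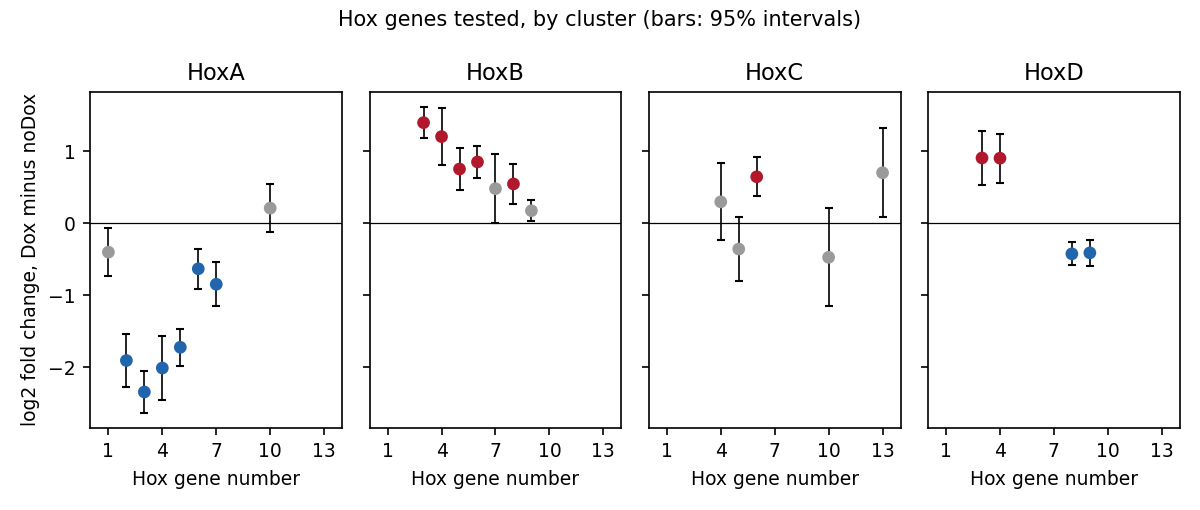
Log2 fold change (Dox minus noDox) of the 24 Hox genes tested, against the gene's number in its cluster, for clusters A to D, from the authors' deposited table. Bars are 95% intervals, and red, blue and grey mark genes higher, lower and not called. Called HoxA genes lie below 0, down to -2.34, and called HoxB genes above 0, up to 1.40.

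Lists of genes from tissues in which CDX2 is known to act were not called by the set test at the floor of 10 counts. That test looks for a shift in 1 direction, so a list with many rises and falls can go uncalled. The counts below stand beside a share of 24.7% called over all genes tested. Of 5 intestinal epithelial genes tested, Klf5 rose (0.28 ± 0.081), Ceacam1 fell (-0.51 ± 0.085) and 3 did not pass in the authors' deposited table, with the same counts adjusted over the list alone (set test adjusted p 0.970), while 16 of the 40 listed had no reads. Under the count floor, where folds rest on few reads, Cdh17 and Cyp2c65 of this list were higher (adjusted p 0.00287 and 0.0131) in the authors' deposited table, as were Hes7 of the posterior axis list, Hoxb2 and the keratin gene Krt19 of the junction list (adjusted p 0.002, 1.55e-04 and 2.07e-07). Trophoblast genes had 4 rises and 3 falls among 10 in the authors' deposited table, also when adjusted over the list alone. Gata3 (1.51 ± 0.25) and Fgfr2 (1.11 ± 0.14) were among the 4 that rose in the authors' deposited table. Tfap2a (-1.08 ± 0.071), Id2 (-1.90 ± 0.15) and Tead4 (-0.84 ± 0.067) fell in the authors' deposited table. The set test gave an adjusted p of 0.219, and of 0.0422, lower, at a floor of 50 counts, which leaves out Gata3. Among 8 posterior axis and Wnt genes, the Wnt target Axin2 (1.26 ± 0.15) and Lef1 (0.61 ± 0.10) rose and Lfng (-1.14 ± 0.11) and Greb1 (-1.98 ± 0.28) were among 3 that fell in the authors' deposited table, with 2 rises and 3 falls adjusted over the list alone (set test adjusted p 0.772). In the intestinal, trophoblast and posterior axis lists the median log2 fold change lay above 0 (0.13, 0.10 and 0.084) and the mean below 0 (-0.050, -0.045 and -0.14). Pluripotency genes had 2 rises (Dppa4 0.43 ± 0.091, Dppa2 0.41 ± 0.10) and 2 falls (Klf4 -0.81 ± 0.062, Klf2 -0.61 ± 0.067) among 6 in the authors' deposited table, with the same counts adjusted over the list alone (set test adjusted p 0.285). The intestinal, trophoblast, posterior axis and pluripotency lists had 0 rises and 0 falls, 1 and 3, 1 and 2, and 0 and 2 with widened standard errors.

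Epithelial junction genes had 3 falls and 0 rises among 11 in the authors' deposited table, 4 and 0 adjusted over the list alone. Cdh1, which encodes E-cadherin (-1.62 ± 0.22), and Grhl2 (-0.82 ± 0.15) were among those that fell in the authors' deposited table (set test adjusted p 0.185). There were 2 falls and 0 rises with widened standard errors.

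Signalling lists moved in both directions, which a set test for a shift in 1 direction can miss. Immediate early genes had 13 rises and 9 falls among 28 in the authors' deposited table, 14 and 9 adjusted over the list alone, with Egr1 (1.37 ± 0.071) and Egr2 higher and Myc (-1.30 ± 0.065) and Spry2 (-0.81 ± 0.072) lower (set test adjusted p 0.146). TGF-beta and BMP response genes had 6 rises and 7 falls among 18 in the authors' deposited table, 6 and 8 adjusted over the list alone. Id3 (-1.78 ± 0.086), Id2 and Id1 (-0.78 ± 0.075), BMP-responsive inhibitors of differentiation, fell in the authors' deposited table (set test adjusted p 0.340). YAP and TEAD targets had 4 rises and 6 falls among 19 in the authors' deposited table, with the same counts adjusted over the list alone (F3 0.74 ± 0.091, Ccn1 0.38 ± 0.064, Asap1 -0.55 ± 0.064; set test adjusted p 0.772). Contractile and actin genes had 3 rises and 8 falls among 25 in the authors' deposited table, 3 and 9 adjusted over the list alone (Tpm1 0.39 ± 0.067, Fhl2 -0.94 ± 0.074, Zyx -0.54 ± 0.065; set test adjusted p 0.270). The 4 lists had 7 rises and 6 falls, 3 and 4, 1 and 2, and 0 and 2 with widened standard errors.

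Stress lists were not called by the set test. Integrated stress response genes had 3 rises and 11 falls among 27 in the authors' deposited table, 3 and 14 adjusted over the list alone, and Slc7a11, a cystine transporter gene, fell (-0.99 ± 0.076) while Ddit4 rose (0.61 ± 0.10) (set test adjusted p 0.142, and 0.0305 with ranks). The p53 targets had 6 rises and 4 falls among 21 in the authors' deposited table, 7 and 7 adjusted over the list alone, with Cdkn1a higher (0.61 ± 0.064) and Plk2 lower (-1.35 ± 0.067) (set test adjusted p 0.672). Interferon response genes had 2 rises and 1 fall among 10 in the authors' deposited table, 2 and 2 adjusted over the list alone (Stat2 0.60 ± 0.11, Irf1 0.54 ± 0.10, Ifit2 -0.70 ± 0.072; set test adjusted p 0.936). These 3 lists had 0 rises and 1 fall, 2 and 1, and 0 and 1 with widened standard errors.

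3 lists hold genes of chromatin structure, the subject of the series title. Of 26 cohesin, CTCF and condensin genes, 3 rose and 2 fell in the authors' deposited table, also when adjusted over the list alone, with Esco1 (0.38 ± 0.083) and Smc2 (0.21 ± 0.065) higher and Zfp143 (-0.28 ± 0.081) and Stag1 (-0.23 ± 0.066) lower. Of 27 lamina and heterochromatin genes, 1 rose and 5 fell in the authors' deposited table, also when adjusted over the list alone. Syne2 rose (0.38 ± 0.066) and Hmga2 (-0.40 ± 0.060), Lmna (-0.31 ± 0.058) and Syne1 (-0.36 ± 0.073) fell in the authors' deposited table. Of 35 Polycomb and SWI/SNF genes, 6 rose and 3 fell in the authors' deposited table, also when adjusted over the list alone, with Cbx8 (0.51 ± 0.093) and Jarid2 (0.43 ± 0.072) higher. The set test called none of the 3 lists (adjusted p 0.503, 0.705 and 0.503), beside a share of 24.7% called over all genes tested. They had 0 rises and 0 falls, 0 and 1, and 1 and 0 with widened standard errors.

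Of 46 cytosolic ribosomal protein genes and 33 nuclear oxidative phosphorylation genes, 0 were called in either direction in the authors' deposited table, also when adjusted over each list alone (limma's cameraPR, adjusted p 0.649 and 0.705). At an unadjusted p under 0.05 there were 0 and 2. Sdha had the smallest p of the second list (-0.17 ± 0.065, adjusted p 0.0546) in the authors' deposited table. The ribosomal protein genes had a median log2 fold change of -0.042. Setting it to 0, with p adjusted over the genes tested, gave 2119 genes higher and 1460 lower. The share of rises among called genes was 45.7% in the authors' deposited table, 46.4% with that adjustment alone and 59.2% with the scaling. Nuclear-retained noncoding RNAs had 1 rise and 4 falls among 15 in the authors' deposited table, 1 and 5 adjusted over the list alone, with Neat1 lower (-0.64 ± 0.063) and Malat1 at -0.10 ± 0.057 (adjusted p 0.284; set test adjusted p 0.233). Adipogenic genes had 0 rises and 3 falls among 7 in the authors' deposited table, also when adjusted over the list alone (Cebpd -0.70 ± 0.10, Fasn -0.34 ± 0.058; set test adjusted p 0.185). The noncoding RNAs and the adipogenic genes each had 0 rises and 1 fall with widened standard errors.

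Markers of other cell types were mostly under the count floor. Of 13 endothelial markers 1 was tested, Cdh5 (-0.23 ± 0.12, adjusted p 0.258), and of 15 leukocyte markers 3 were tested, of which Cd14 rose (0.55 ± 0.10), in the authors' deposited table, also when adjusted over the list alone, and 0 of these 4 were called with widened standard errors. Of 20 muscle and neural markers 8 were tested, and the list was not called by the set test (adjusted p 0.723).

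The standard errors in the authors' deposited table follow expression level and fold rather than each gene's own replicates, and with all of them widened by 2.08 there were 190 genes higher and 386 lower. The factor was taken from t over all genes tested, changed genes included, so these counts do not show the spread between replicates. None of the 4 libraries came from doxycycline-treated cells without the transgene, so effects of doxycycline and of CDX2 are not separated.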

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

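The alternatives other than the 2 count floors, the threshold of 0.01 and lists without shared members were chosen after seeing the data. No paired analysis was possible because the table gives a comparison and no values per library; for the same reason the other size factors, library totals, DESeq2, limma-voom, the replicate block, each left-out replicate, the estimated correlation, fry and the pseudocounts were not run. Cdx2 was called higher under each alternative run for single genes, and under each run for lists between 2 and 4 lists were lower, against 3, and 1 was higher. Against 1393 genes higher and 1654 lower, widened standard errors gave 190 and 386, a test against a 1.2-fold change 288 and 448, and scaling to ribosomal protein genes 2119 higher (59.2% of its calls, against 45.7%). These follow from the alternatives' construction. Widened standard errors, the 1.2-fold test, removal of the trend and scaling also adjusted p over the genes tested. That adjustment alone gave 1575 genes higher and 1817 lower. Of 73 genes at least 2-fold higher, a floor of 50 counts left 39 and widened standard errors 41, while without a floor there were 179, and 271 in place of 134 lower. Of 122 named genes tested (Gata3 and Duox2 not counted), 38 lost their call with widened standard errors and 33 against a 1.2-fold change, and 0 turned direction. A threshold of 0.01 ended 2 calls, and adjustment over the genes tested, removal of the trend and scaling to ribosomal protein genes added 3, 3 and 1. Fibroblast matrix genes were not called without the expression trend (adjusted p 0.220; the other alternatives 1.85e-04 to 0.0308), nor NF-kappaB and cytokine genes by ranks (0.379; the others 2.16e-11 to 4.48e-06). Integrated stress response genes were called without a floor (0.0421) and by ranks (0.0305, the others 0.0989 to 0.384), and the cause was not tested. Trophoblast genes were called at a floor of 50 counts (0.0422, the others 0.218 to 0.839). That floor kept 8 of the 10 trophoblast genes and left out Gata3 and Duox2, whose log2 fold changes were above 0 (1.51 and 0.35). The mean t of the list thereby moved from -2.02 to -3.43. Of simulated log2 changes of 0.25, 29.6% were recovered at the table's standard errors, whose median was 0.22 in the 2471 genes with the lowest mean level and 0.065 in the 2471 with the highest, so depth limits calls at low levels and the effect of depth elsewhere was not tested.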

Other observations

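The tests of the standard errors and of overlapping Hox transcripts were chosen after the result was seen, as were the gene families named here and the counts by span, length, level and isoform, and the tests of neighbours that point away from each other and of neighbours within classes of expression and span were added after the excess of neighbours had been seen.

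Gene families were scanned by symbol root, 129 with at least 10 tested members, some of which share members with the fixed lists. Only the Pcdhga group of clustered protocadherins, cell adhesion genes, was past the set test (12 genes, adjusted p 1.58e-07). All 12 fell in the authors' deposited table, with a median log2 fold change of -0.38, and they share their 3' exons, so they are close to 1 measurement. Kruppel-like factors had 7 falls and 2 rises among 12 in the authors' deposited table, with Klf4 (-0.81 ± 0.062), Klf2 (-0.61 ± 0.067) and Klf9 (-0.58 ± 0.068) lower and Klf10 (0.26 ± 0.073) higher, and missed the threshold (adjusted p 0.0615). Utp genes of ribosomal RNA processing had 6 falls and 0 rises among 11 (Utp4 -0.36 ± 0.070, Utp18 -0.35 ± 0.069 in the authors' deposited table; adjusted p 0.136). Of the 2471 genes with the longest genomic span, 22.3% were lower and 9.19% higher, against 9.11% and 8.94% of the 2471 with the shortest. The share lower differed alike by exon length (22.5% of the longest, 5.22% of the shortest) and by mean level (22.5% of the highest, 7.20% of the lowest), and these were not separated. No isoform pair was called in opposite directions among 5573 genes with more than 1 transcript above the floor (0 genes). Transcripts of a gene can share exons and so reads, which ties their fold changes. The count therefore says little about changes between isoforms.

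Neighbouring genes changed in the same direction more often than chance gives. Among 10896 adjacent tested pairs without overlap, 489 were called the same way, against a mean of 339 in 10000 permutations within expression classes (p = 0.0001, the smallest these can give). Read-through cannot join pairs that point away from each other, whichever strand is counted, and related copies have like symbols, but the ratio to the permuted mean was 1.45 for pairs that point away and 1.39 for pairs with different symbol roots. With calls permuted within classes of both expression and span it was 1.42, which argues against like length and level of neighbours. The ratio was 1.32 at gaps under 50 kb and 1.86 over 200 kb, while that of pairs called in opposite directions was 0.660 and 1.21 (0.816 over all pairs), and no biological explanation was tested.

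The share of called genes, 24.7%, was weighed against pooled standard errors and the expression trend. Standard errors too small for every gene alike would widen t everywhere. Over 79 ribosomal protein and oxidative phosphorylation genes the SD of t was 0.785 (bootstrap interval 0.623 to 0.930). The robust SD was 2.08 over all genes tested and 0.602 over the 79. So t over these 79 genes was no wider than the standard errors give. The test was chosen after the results were seen, and 0 of these 79 genes were called, which bounds the size of their t. At an unadjusted p under 0.05 there were 0 of 46 ribosomal protein genes and 2 of 33 oxidative phosphorylation genes. Genes of these lists may also vary together, which the bootstrap over genes does not allow for, so the test does not decide the question. With the trend removed and p adjusted over the genes tested, which is laxer than the authors' adjustment, 91.5% of called genes kept their call and direction. Errors too small for every gene alike, or for genes that vary more between cultures, stay open, since no values per library were analysed here.

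HoxA genes had a mean log2 fold change of -1.21 over 8 genes tested and HoxB genes 0.77 over 7. This difference was noticed in the data. Its exact permutation p (two-sided, 6.22e-04) treats genes as independent, although overlapping rows may share reads and genes of 1 cluster may change together. Over 3 HoxA and 4 HoxB rows that overlap no other gene in the authors' deposited table the permutation p was 0.114. The smallest possible there is 0.0571, so that test cannot pass 0.05. Over the 4 HoxB rows that overlap no other gene in the authors' deposited table or in GENCODE M21 (Hoxb4 1.2 ± 0.20, Hoxb7 0.48 ± 0.24, Hoxb8 0.55 ± 0.14, Hoxb9 0.18 ± 0.076) the mean was 0.60, with a 95% interval of 0.24 to 0.96 from standard errors widened by 2.08, which argues against shared reads as the whole of the HoxB rise. That interval treats the 4 rows as independent. Of these rows 2 were called, Hoxb4 and Hoxb8, and both calls were lost with widened standard errors. Over the 2 HoxA rows without such overlap (Hoxa7 -0.85 ± 0.16, called, and Hoxa10 0.21 ± 0.17, not called) in the authors' deposited table the mean was -0.32 (-0.79 to 0.15), so shared reads stay open for the HoxA fall. Hoxa2 (-1.90 ± 0.19, called lower) was left out of that mean because it overlaps Gm28308 in GENCODE M21. It overlaps no other gene in the authors' deposited table. A response to doxycycline alone cannot be told apart from a response to CDX2, since 0 of the libraries are from treated cells without the transgene.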
